A study of Mus musculus with 17 samples.

How the data were processed

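Total RNA of 17 mouse samples was read as biotin-labelled cRNA on Illumina BeadArrays, with 1 array per condition. The labels give ESC (1 array), cells with tetracycline-controlled Oct4 from MEF, NSC and BMC at 0, 6, 12 and 24 h (4 arrays each), and wild-type MEF and NSC at 0 and 24 h. The inducing compound is not named in the labels, so the text says treatment. The labels give the 0 h arrays of the transgenic lines as treated, and for the wild-type MEF array at 24 h a source field gives 14 where its title gives 24. Times were taken from the titles. All 17 arrays were used, and every array column of the files was assigned to a condition (0 columns unassigned).

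The deposited table of probe values holds an intensity per probe and array on a linear scale, without normalization, and a detection p-value against the negative control beads, as the authors exported them. The authors' series matrix holds log2 values. Per the submitters' processing notes BeadStudio 3.2, RMA and lumi were used, with no order or settings. From the values, the log2 columns share the same quantiles (median 3.77 on each array) and keep the rank order of the intensity columns (Spearman correlation 1), so they were read as background-corrected and quantile-normalized, which the notes do not state. The array table holds 25697 probes, of which 23978 carry 1 gene symbol and 1719 none. Symbols of 23962 probes were looked up by Entrez number in the mouse gene table, and 0 changed. Older symbols in the gene lists were matched to current ones.

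Log2 values were made from the intensities with limma 3.58.1 in R 4.3.3: normexp background correction with the mean and SD of negative controls inferred from the detection p-values, an offset of 16, and quantile normalization over the 17 arrays. Probes with a detection p under 0.01 on at least 1 array were kept (15543, of which 14637 with a symbol, from 10572 genes). Each array detected 39.8 to 43.1 percent of all probes, and the median raw intensity was 97.5 to 139. Where a probe was not detected on an array of the dimmer side, the lowest log2 signal among detected probes on that array, or the probe's own signal if higher, was used there, and the fold is given as a lower bound. Medians of some lists at 24 h are also given with such members at their bound, and at 0 where both sides were below background, an addition made after seeing the data.

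With a single array per condition no condition could be tested against another on its own. The 16 somatic arrays were fitted together in limma with an intercept for each of 5 cell lines and an induction term per cell type, which was 1 at 6, 12 and 24 h and 0 otherwise (8 residual and 3.61 prior degrees of freedom). The error is the spread between the 3 times and between the wild-type arrays, so a change that builds up over time enlarges it. P-values came from empirical Bayes moderated t-tests and were adjusted by the Benjamini-Hochberg method over probes, with 0.05 as threshold. The mean of the 3 terms and their differences were tested in the same fit. A linear trend over 0, 6, 12 and 24 h replaced the induction term as an alternative, and the value given for it is the fitted change over 24 h. The trend with the wild-type trend subtracted (6 residual degrees of freedom) was added after seeing the data.

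In simulated data of the same layout and 15543 probes, steps of log2 size 1, 2 and 3 in 66 or 67 probes each were found in 22.4, 85.1 and 98.5 percent of cases in MEF by the step test. Ramps of these sizes were found in 7.46, 71.6 and 97.0 percent by the trend. The step test found 0 ramps and the trend 0 steps. False calls numbered 5 to 12 per cell type for steps and 4 to 11 for ramps. The simulated noise was independent between probes and arrays. These counts therefore do not cover false calls from correlated genes or from drift of a single culture.

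The 21 gene lists were fixed before the data were examined: pluripotency, epithelial, mesenchymal (fibroblast markers), neural stem and progenitor, neuronal, myeloid and macrophage, lymphoid, erythroid and progenitor blood, trophectoderm, primitive endoderm and mesendoderm, cell cycle, p53 targets and senescence, interferon response, NF-kB and inflammatory cytokines, TGF-beta and serum response, immediate early, Atf4 targets, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, histone and DNA methylation regulators, and ribosomal proteins. They were tested with limma camera at a preset correlation of 0.01 between genes, with the probe of highest mean per gene, at least 5 measured members, and adjustment over 21 lists and 4 contrasts. An estimated correlation and limma fry served as alternatives. List medians were compared with 10000 random lists (seed 1). A count adjusted over the list alone used the Benjamini-Hochberg method on the p-values of that list's members only.

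Genes were named by a rule set before the data were examined. Pou5f1 was always named. Per cell type and for the mean, the 10 largest rises and falls past the threshold with the same sign at 6, 12 and 24 h were named, filled up where fewer passed by genes with the largest smallest change over the 3 times, given as values. For wild-type cells and ESC the 5 largest in each direction among detected genes were named, and from each list up to 4 members with the largest mean change, as well as any pluripotency gene detected after induction and not at 0 h. Further list members, and the granulocyte and macrophage genes, were named after their values were seen. Differences of at least 2-fold from 0 h were counted without a test where the probe was detected on either array.

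Alternatives were the authors' log2 values, no background correction, an offset of 50, median scaling, quantile normalization within each cell type, and no detection filter or detection on at least 3 arrays. Others were no cell line term, a treatment term shared with wild-type cells, the wild-type arrays left out, a separate fit per cell type, an intensity trend with a robust prior, a 1.5-fold limit, and leaving out 1 array at a time. The trend was repeated without each of the 16 somatic arrays, and the step test without each of 13, which excludes the 0 h arrays of the induced lines. ESC were left out of the fits because they have no time course. Wild-type BMC were not analysed here.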

Results

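Gene expression was measured in 17 mouse samples, each on 1 Illumina BeadArray of 25697 probes. Embryonic stem cells (ESC), the pluripotent cells in which Oct4 is normally active, were measured on 1 array. Cells carrying Oct4 under tetracycline control were taken from 3 cell types, namely embryonic fibroblasts (MEF), neural stem cells (NSC) and bone marrow cells (BMC), and each was measured at 0, 6, 12 and 24 h. Wild-type MEF and NSC, which lack the transgene, were measured untreated and after 24 h of treatment. The title of the series places the comparison in the first steps of reprogramming, and the design asks what Oct4 on its own does to 3 kinds of somatic cell within 24 h. No condition had a repeat array. A change was therefore tested as the mean of 6, 12 and 24 h against 0 h of the same line, with the spread between times and between wild-type arrays as its error, so an error or p given here does not measure variation between cultures. Each array detected between 10231 and 11082 probes, and 15543 probes detected at least once were tested. The mean raw intensity was 382 to 437 on the induced-line MEF arrays and 548 to 672 on all others, so these 4 arrays were dimmer than the rest before normalization.

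Pou5f1, the gene for Oct4, was read by a pair of probes, and both rose in all 3 cell types. Since Oct4 is the induced gene, this rise checks the labels and does not show that the endogenous gene was switched on. In MEF the log2 level rose from 8.41 at 0 h, where it was already detected, by 5.87 ± 0.35 (SE, limma adjusted p = 1.37e-05). At 6, 12 and 24 h it stood at 2.12, 2.62 and 2.93 times the level of ESC by the same probe, and at 1.93, 2.28 and 2.55 times by the other. Before normalization the intensities of the first probe were 13003, 17681 and 16358, against 9126 in ESC. The normalized ratios thus depend on the scaling of the dimmer MEF arrays. In NSC and BMC the 0 h signal was below background, and the induced level was at least 32.5-fold higher in NSC and at least 45.9-fold higher in BMC. The log2 levels were 10.24, 11.20 and 10.22 in NSC and 11.09, 11.08 and 10.85 in BMC at the 3 times, all under the 12.94 of ESC. By the other probe the change was 5.87 ± 0.32 in MEF, at least 35.7-fold in NSC and at least 50.5-fold in BMC. Wild-type MEF and NSC did not show a detectable signal at 0 or 24 h. Here and below, a fold given as at least N-fold sets the brighter side against the dimmer arrays. The lowest signal among detected probes stood in on each array that did not detect the probe, unless the probe's own signal was higher.

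**Figure D1:**
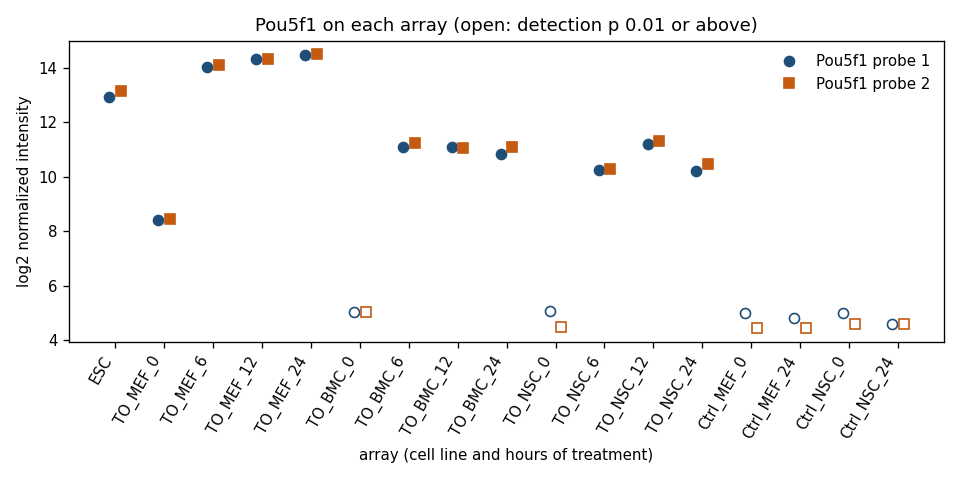
Log2 level of Pou5f1 on each of the 17 arrays, by cell type and hours of induction, with ESC and wild-type arrays for comparison. On the probe quoted above, the levels after induction lay above the 12.94 of ESC in MEF and below it in NSC and BMC.

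Induced MEF lowered Ccl7, Scx, Vdr and Pdgfrb and raised Arid5b, Epha1 and Tle4, among 30 probes past the threshold. The chemokine gene Ccl7 fell by 3.10 ± 0.50 on the log2 scale (SE, limma adjusted p = 0.0358), and the mesenchymal growth factor receptor gene Pdgfrb by 2.04 ± 0.35 (adjusted p = 0.0492). The tendon transcription factor gene Scx (at least 4.18-fold, adjusted p = 0.0188) and the vitamin D receptor gene Vdr (at least 4.08-fold, adjusted p = 0.0221) fell to levels detected on 1 of the 3 later arrays. Mrgprf (-2.39), Ier5l (-2.34), Clec2d (-1.96), Tnfaip2 (at least 3.69-fold), the gap junction gene Gjb2 (at least 2.94-fold) and Fam180a (at least 2.5-fold) fell as well, with adjusted p between 0.00402 and 0.0358. Besides Pou5f1, the genes that rose were Arid5b, a DNA-binding regulator, by 1.81 ± 0.22 (adjusted p = 0.00935), and Epha1, an ephrin receptor, by 1.51 ± 0.23 (adjusted p = 0.026). Tle4, a co-repressor, rose by 1.46 ± 0.25 (adjusted p = 0.0485), as did Map7d3 (at least 3.89-fold) and the protocadherin gene Pcdh9 (at least 2.95-fold). For Tle4, 1 of 2 other probes had the same sign. Wild-type MEF moved by between -0.54 and 0.71 in these genes over 24 h, a movement that enters the error of the step test. Genes that pass are thus partly chosen for a small one.

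In all, 30 probes passed in MEF, 7 higher and 23 lower, and 1439 had an unadjusted p under 0.05 where 777 are expected by chance. Changes that built up over the day counted as spread in that test. A linear trend over 0 to 24 h, an alternative fixed before the data were examined, called 1710 probes, of which 950 rose and 760 fell. It called 396 without the 24 h MEF array and 859 without the 0 h MEF array. The choice to report it beside the step test was made after the data had been seen. Its called probes had a median 24 h change of 1.26 (rose) and -1.33 (fell) in the induced line and of 0.00 and -0.01 in wild-type MEF, and 177 probes were called when the wild-type trend was subtracted, a fit added after seeing the data. That fit has fewer degrees of freedom and takes the wild-type slope from 2 arrays. In the trend without that subtraction the wild-type difference counts as error. The contrast of the medians is therefore partly set by the choice of called probes. The number of probes differing at least 2-fold from 0 h grew from 340 at 6 h to 874 at 12 h and 1723 at 24 h, against 33 in wild-type MEF after 24 h. That last count was 401 with the authors' values and 3 with an offset of 50.

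Among the fixed lists, the interferon response genes, which cells switch on during antiviral defence, rose in MEF (preset-correlation camera, adjusted p = 0.00774, but adjusted p = 0.954 with an estimated correlation). Their median change was -0.05, 0.46 and 1.68 at 6, 12 and 24 h and -0.09 in wild-type MEF, whose median level at 0 h was already higher (6.85 against 5.36), and without background correction the 24 h median was 0.82. With members below background at their bound, or at 0 where both sides were below it, the 24 h median was 1.19. By the trend 12 of 22 measured members rose and none fell, or 15 when adjusted over the list alone, and 4 rose with the wild-type trend subtracted. Usp18, which removes the ubiquitin-like modifier encoded by Isg15, gained 4.65 ± 0.34 over 24 h (limma adjusted p = 1.55e-05), Ifit3 3.96 ± 0.52 (adjusted p = 0.00051) and Isg15 itself 3.91 ± 0.62 (adjusted p = 0.00175). The immunity-related GTPase gene Igtp ended at least 8.1-fold above 0 h, and the regulators Irf7, Irf9 and Stat2 also rose. None of the 22 passed in the step test.

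Genes of amino acid supply and unfolded protein stress, targets of Atf4, fell in MEF (adjusted p = 5.06e-05, and 0.954 as adjusted p with an estimated correlation), with a median of -1.16 at 24 h against 0.07 in wild-type MEF. By the trend 10 of 24 fell, 15 when adjusted over the list alone and 1 with the wild-type trend subtracted. Among the 10 were Chac1 (-2.11 ± 0.51, adjusted p = 0.019), the mitochondrial serine enzyme gene Shmt2 (-1.95 ± 0.30, adjusted p = 0.00139), Trib3 (-1.74 ± 0.37, adjusted p = 0.00956) and Atf4 itself (-1.22 ± 0.27, adjusted p = 0.0108). Targets of TGF-beta and serum fell as a list (adjusted p = 0.0082, and 0.954 as adjusted p with an estimated correlation), with 7 of 15 lower by the trend, 10 when adjusted over the list alone and 1 with the wild-type trend subtracted. The cardiac and stretch-response gene Ankrd1 had the largest loss among these 7, -4.12 ± 0.40 (adjusted p = 9.65e-05), followed by Id3 (-2.39) and the matricellular gene Ccn1 (-1.77). Immediate early genes (adjusted p = 0.00176) and NF-kB and inflammatory genes (adjusted p = 0.0093) fell too, both with an adjusted p of 0.954 with an estimated correlation. Of the former, Junb (-2.52) and Fosl1 (-1.76) fell among 14 by the trend, 4 when adjusted over the list alone and 1 with the wild-type trend subtracted. Of the latter, 6 of 17 fell, 8 when adjusted over the list alone and 0 with the wild-type trend subtracted. The 6 included Ccl2 (at least 5.42-fold at 24 h), the adhesion gene Vcam1 (-1.67) and the NF-kB inhibitor gene Nfkbia (-1.27). Of the 17 members, 8 lay below background at both 0 and 24 h, and the 24 h median of -0.405 was 0 with members at their bound. The step test passed Ccl7 alone in that list, and 1 higher and 5 lower members when adjusted over the list alone.

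Neuronal marker genes rose in MEF as a list (adjusted p = 0.0227, and 0.954 as adjusted p with an estimated correlation), carried by 4 of 11 members that passed by the trend, the same number when adjusted over the list alone and 2 with the wild-type trend subtracted. The 4 were the neurofilament gene Nefm (at least 14.7-fold at 24 h), the growth cone gene Gap43 (4.37 over 24 h, adjusted p = 0.000268), the dendritic microtubule gene Map2 (2.87, adjusted p = 0.00129) and Stmn2 (at least 3.74-fold at 24 h). Of the 11 members, 7 lay below background at both 0 and 24 h. The list's 24 h median of 0.37 was 0 with members at their bound. Scg5, a secretory chaperone gene of endocrine and neural cells, and Hs3st1, a heparan sulfate sulfotransferase gene, rose by the trend (adjusted p = 0.000645 and 0.0162). Scg5 was at least 8.13-fold higher over the 3 times and Hs3st1 gained 5.01 over 24 h, with step-test adjusted p of 0.0889 and 0.214. Fibroblast markers did not pass as a list (adjusted p = 0.225), yet the repressor of epithelial genes Snai1 (-2.71), Pdgfrb (-2.05), the collagen crosslinking gene Lox (-1.61) and the smooth muscle gene Tagln (-1.51) fell by the trend and the proteoglycan gene Dcn rose (1.10). With the list adjusted alone 8 fell and 2 rose of 27, and 0 passed with the wild-type trend subtracted. The neural stem and progenitor list fell by the trend (adjusted p = 0.0453, adjusted p = 0.71 with an estimated correlation) and not in the step test (adjusted p = 0.0806). Of 16 members, 11 lay below background at both 0 and 24 h, and the list's 24 h median of -0.156 was 0 with members at their bound. Of its members the glutamate transporter gene Slc1a3 (at least 11.8-fold at 24 h), Cspg4 (-2.09), Nes (-1.87), Notch1 (at least 2.88-fold) and Sox9 (at least 2.42-fold) fell by the trend, 5 of 16 also when adjusted over the list alone and 0 with the wild-type trend subtracted. Without the 6 h MEF array the step test called 425 probes, and without the 12 h BMC array 6.

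**Figure D2:**
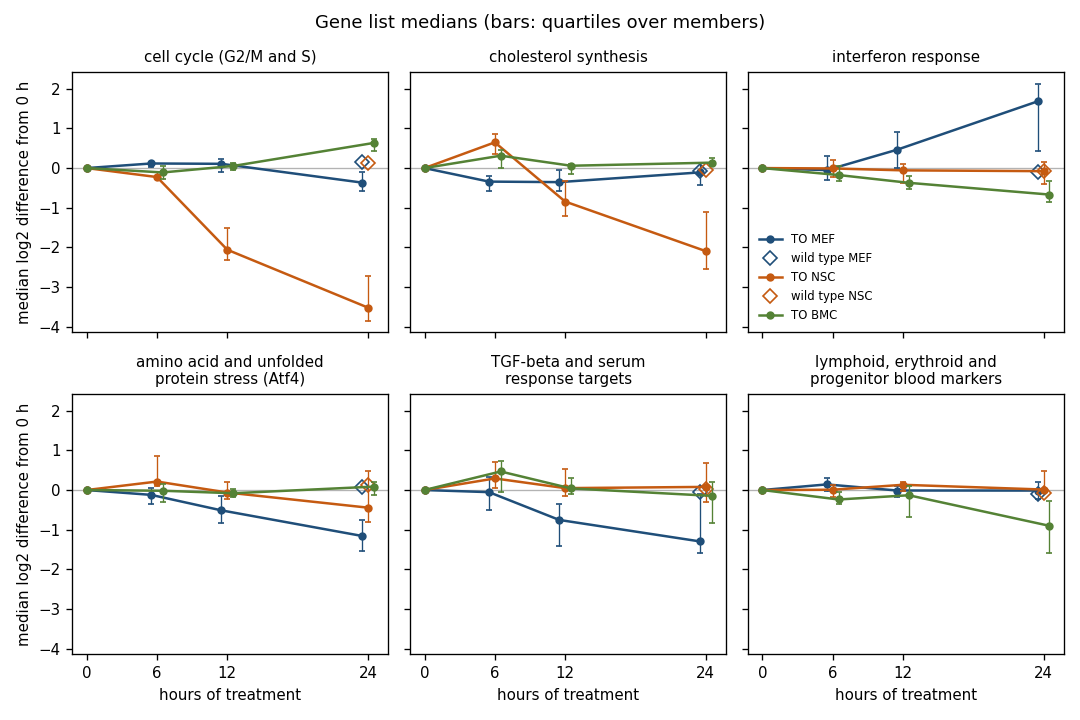
Median log2 difference from 0 h of selected fixed gene lists at 6, 12 and 24 h of induction in each cell type, with the 24 h change in wild-type MEF and NSC. At 24 h the interferon median was 1.68 in MEF and -0.67 in BMC, and the cell cycle median was -3.51 in NSC.

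Transcripts of cell division genes were lower in the induced NSC cultures at 12 and 24 h. All 24 measured genes of the cell cycle list fell by the trend, also when adjusted over the list alone, and the list's median was -0.23 at 6 h, -2.06 at 12 h and -3.51 at 24 h, against 0.12 in wild-type NSC after 24 h. With the 7 members below background at 24 h set to their bound it was -3.50, and 17 of the 24 were still detected then. The replication licensing gene Mcm5 changed by -4.75 ± 0.38 over 24 h on the log2 scale (limma adjusted p = 3.56e-05), and the licensing factor gene Cdt1 by -4.58 ± 0.40 (adjusted p = 3.97e-05). The mitotic kinase gene Cdk1 changed by -4.38 ± 0.49 (adjusted p = 0.000103) and the topoisomerase gene Top2a by -4.14 ± 0.45 (adjusted p = 8.41e-05). Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, and Cdc6 ended at least 13.3-fold and at least 11.7-fold lower. The list test gave adjusted p = 8.48e-12 in the step fit, lost with an estimated correlation (adjusted p = 0.954), and no member passed on its own there, since the fall came after 6 h. When the wild-type trend was subtracted, all 24 remained past the threshold.

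Cholesterol synthesis genes in NSC turned from a median of 0.65 at 6 h to -0.84 at 12 h and -2.09 at 24 h, against -0.04 in wild-type NSC. By the trend 15 of 18 fell, 17 when adjusted over the list alone and 6 with the wild-type trend subtracted. The enzyme genes with the largest falls were Msmo1 (-3.98 ± 0.52, adjusted p = 0.000245), Lss (-3.74 ± 0.69, adjusted p = 0.00225), Cyp51 (-3.60 ± 0.58, adjusted p = 0.00101) and Fdps (-3.32 ± 0.58, adjusted p = 0.00165). The step list test gave adjusted p = 0.023 (adjusted p = 0.954 with an estimated correlation), and without the 24 h arrays it gave 0.966 with the direction turned. The oxidative phosphorylation list was lower by a median of -0.12 (adjusted p = 0.0225, and 0.954 as adjusted p with an estimated correlation). Cycs (-1.45), Atp5o (-0.97) and Sdhb (-0.69) fell by the trend, 3 of 24, also 3 when adjusted over the list alone and 0 with the wild-type trend subtracted. The maintenance DNA methylation genes Uhrf1 (-4.04) and Dnmt1 (-2.79), which dividing cells use, fell by the trend, and the growth cone gene Gap43, which rose in MEF, fell here by 3.32 (adjusted p = 0.000669). Among neural stem and progenitor markers the Notch target Hes5 (2.31, adjusted p = 0.00391), the glial regulator Sox9 (1.47), Bcan and Cspg4 (1.12) rose and Fabp7 (-1.46) fell. These were 4 and 1 of 16, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.83). With the wild-type trend subtracted 0 rose and 2 fell, and in wild-type NSC the list had a median of 0.18 at 24 h with 11 of 16 higher.

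The genes that rose in NSC from 6 h on were led by Liph, a phospholipase gene (at least 21.8-fold, limma adjusted p = 0.045), and Sult1a1, a sulfotransferase gene (at least 15.3-fold, adjusted p = 0.0377). By fitted change they were followed by Cav1, which encodes the caveolar coat protein caveolin-1 (4.14 ± 0.36, adjusted p = 0.000529), and Fam107a (at least 8.24-fold, adjusted p = 0.0019). The lower bounds do not settle this order. These 4 were also higher in wild-type NSC after 24 h, by 1.59, 1.78, 0.92 and 1.47. Rnf125 (at least 5.37-fold), the metallothionein gene Mt2 (at least 4.64-fold), Dbndd1 (at least 3.17-fold), Adamts19 (at least 3.13-fold) and Rbms1 (1.95 ± 0.25) rose as well, with adjusted p between 0.0117 and 0.0489, and 1 of 2 other Rnf125 probes had the same sign. The potassium channel gene Kcnc4 fell at least 6.57-fold (adjusted p = 0.0241), Kcnip3 fell by 2.63 ± 0.27 (adjusted p = 0.0019) and the BMP regulator gene Bmper by 2.75 ± 0.45 (adjusted p = 0.0362, wild type -0.92). Ahsa2 (-1.92), Kank4 (at least 2.86-fold), the GABA-synthesis gene Gad1 (at least 1.7-fold), Rapgef6 (at least 1.53-fold) and Stx8 (-2.24) fell too. For Stx8, 3 other probes had the opposite sign.

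The step test passed 32 probes in NSC, 21 higher and 11 lower, with 1316 at an unadjusted p under 0.05. The trend called 3617, of which 1851 rose and 1766 fell, and 1301 with the wild-type trend subtracted. The median changes at 24 h of the rising and falling trend calls were 1.14 and -1.20 in the induced line and -0.09 and 0.08 in wild-type NSC. As in MEF, this contrast is partly set by the choice of probes. Probes at least 2-fold from 0 h numbered 486, 1182 and 2554 at 6, 12 and 24 h, against 234 in wild-type NSC, which was 663 with the authors' values and 98 with an offset of 50. Without the 6 h NSC array the step test called 986 probes, without the 6 h BMC array 14, and without the 24 h NSC array the trend called 555.

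BMC had the fewest changed probes of the 3 induced lines in the step test, by the trend and among 2-fold differences, and the falls that passed included granulocyte genes. A separate fit per cell type passed 2 probes in MEF, 0 in NSC and 2 in BMC, and a treatment term shared with wild type left 2, 3 and 2. Ltf, the lactoferrin gene of neutrophil granules, fell at least 2.11-fold (limma adjusted p = 0.00137), Cebpe, a transcription factor gene of granulocyte maturation, fell by 1.71 ± 0.20 (adjusted p = 0.00704) and Asprv1 at least 1.92-fold (adjusted p = 0.00465). Mpo and Elane, which encode granule enzymes made by immature granulocytes, were at least 72.6-fold and at least 27.1-fold lower at 24 h, and passed by the trend (adjusted p = 2.32e-07 and 7.91e-06). The antimicrobial peptide gene Camp (-3.11 over 24 h, adjusted p = 0.00724), Cstdc4 (at least 4.53-fold at 24 h, adjusted p = 0.00429) and the neutrophil chemokine receptor gene Cxcr2 (at least 4.79-fold at 24 h, adjusted p = 0.00172) also fell by the trend and had step-test adjusted p of 0.205, 0.295 and 0.358. Some macrophage genes, picked after their values were seen, stood near 0 h at 24 h, with log2 differences of 0.09 for the complement gene C1qa, -0.12 for Ctss, -0.13 for Laptm5 and 0.14 for Cd14. The myeloid and macrophage list, which also holds Mpo and Elane, had a mean change of -0.27 over the 3 times and a median of 0.04 at 24 h. It did not pass in the step test (adjusted p = 0.83), while fry by the trend passed it as lower (adjusted p = 0.00842). By the trend 2 of 19 were lower, Mpo and Elane, and 4 when adjusted over the list alone.

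The list of lymphoid, erythroid and progenitor blood markers fell in BMC (adjusted p = 0.00306, adjusted p = 0.954 with an estimated correlation), with a median of -0.90 at 24 h, or -0.46 without background correction and -0.31 with members below background at their bound, or at 0 where both sides were below it. Its call by the trend held with an estimated correlation (adjusted p = 0.0179). The megakaryocyte integrin gene Itga2b (-3.08), the mast cell protease gene Cpa3 (at least 3.68-fold), the basophil protease gene Mcpt8 (at least 1.07-fold) and the B cell receptor gene Cd79a (-1.45) fell by the trend, 4 of 12 members and 6 when adjusted over the list alone. Interferon response genes were lower by a median of -0.67 at 24 h (list adjusted p = 0.000728, and 0.954 as adjusted p with an estimated correlation), the opposite sign to MEF. Mx2 (-1.24) and Irf7 (-1.26) fell by the trend, and 8 of 22 when adjusted over the list alone. Cell cycle genes had a median of 0.63 at 24 h, with 23 of 24 higher. Over the 3 times their mean change was 0.18, and the list did not pass in the step test (camera, adjusted p = 0.521). Their list passed by the trend (adjusted p = 2e-09, adjusted p = 0.447 with an estimated correlation) but no member did, on its own or adjusted over the list alone. The NF-kB and inflammatory list passed as lower by the trend (adjusted p = 0.0411, adjusted p = 0.553 with an estimated correlation). Of it Il1b (-1.82) and Ccl5 (-1.12) fell and the neutrophil attractant gene Cxcl1 rose (1.80), and 3 fell and 1 rose when adjusted over the list alone.

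Genes higher in BMC at all 3 times were Parm1 (at least 5.48-fold), Rspo3 (at least 2.7-fold), Medag (at least 2.49-fold), Gnb5 (at least 2.2-fold), Gpr171 (at least 1.88-fold), Pbx3, Rmnd5b, Man1a and Robo1. None of these passed the step test, whose lowest adjusted p among them was 0.0915. Rspo3, which encodes an activator of Wnt signalling, and Medag passed by the trend (adjusted p = 0.0361 and 0.0459). For Rmnd5b the 1 other probe had the opposite sign. Ltb4r1 (-1.61), Esm1 (at least 2.8-fold), Ibsp (at least 2.2-fold) and Adipoq (at least 1.42-fold) were lower, also without passing. Of 5 probes called, or 27 without the 6 h BMC array, 2 read Pou5f1, and 346 had an unadjusted p under 0.05, fewer than the 777 expected by chance. The error of each probe was shared by all somatic arrays, so changes that built up in MEF or NSC could raise the p-values of BMC. The low count is therefore no measure of an absent response. The trend called 120, of which 25 rose and 95 fell, or 23 without the 24 h BMC array and 73 without the 0 h BMC array. Probes at least 2-fold from 0 h numbered 100, 133 and 310 at 6, 12 and 24 h. The 310 became 746 with the authors' values and 151 with an offset of 50. Wild-type BMC were not analysed here, so these changes have no reference without the transgene.

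**Figure D3:**
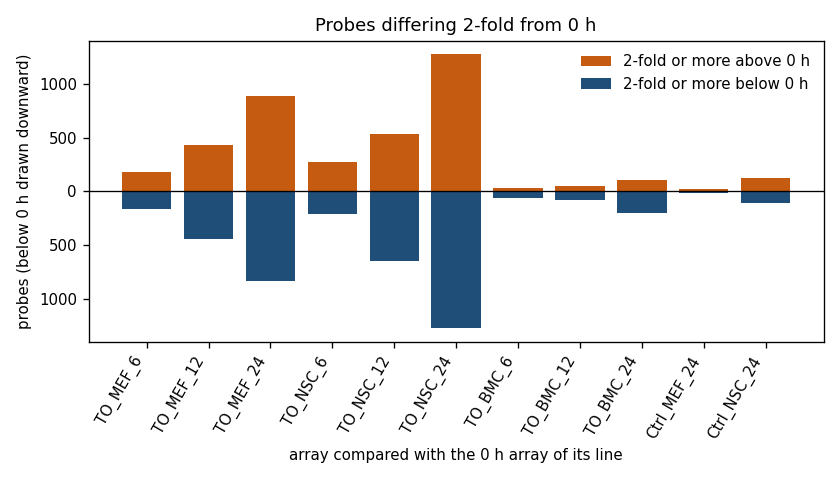
Number of probes at least 2-fold higher or lower than on the 0 h array of the same line at 6, 12 and 24 h, for each cell type and for wild-type MEF and NSC at 24 h. At 24 h the induced lines held 1723 (MEF), 2554 (NSC) and 310 (BMC) such probes, and the wild-type lines 33 and 234.

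On average over the 3 cell types, 10 probes passed, 4 higher and 6 lower, with 1117 at an unadjusted p under 0.05. The count was 4 without the 12 h MEF array and 63 without the 6 h MEF array. These are means of fitted values, and several rested mostly on 1 cell type. Arid5b rose by 1.12 ± 0.13 (limma adjusted p = 0.00712), from 1.81 in MEF, 1.43 in NSC and 0.11 in BMC, and the neurite growth gene Nrn1 by 0.91 ± 0.13 (adjusted p = 0.0389), from 0.93 in MEF and at least 1.84-fold in NSC, below background in BMC. Pdk4, a kinase gene that restrains glucose oxidation, fell by 1.16 ± 0.17 in the mean (adjusted p = 0.0419), from at least 2.55-fold in MEF and at least 2.53-fold in BMC, below background in NSC. The other means past the threshold were Kcnip3 (-1.10 ± 0.16, adjusted p = 0.0389), a second probe of Vdr (-0.88 ± 0.13, adjusted p = 0.0419) and Clec2d (-0.87 ± 0.12, adjusted p = 0.0343). Kcnip3 was lower at least 1.38-fold in MEF and by -2.63 in NSC, and below background in BMC. This Vdr probe was lower at least 2.81-fold in MEF and at least 1.34-fold in BMC, and below background in NSC. Clec2d had -1.96, -0.28 and -0.37 in MEF, NSC and BMC. Ltf also passed as lower (adjusted p = 0.0419), through BMC, where it ended below background. The mean change was 1.28 for Cav1, 1.14 for Dnajc12, 1.08 for Elmo1, -1.23 for the Notch target Hes1 and -1.90 for Fam20a, none of them past the step test. By the trend Elmo1 (1.48, adjusted p = 0.000554) and Dnajc12 (1.32, adjusted p = 0.0165) rose and Hes1 (-1.51, adjusted p = 0.00667) and Fam20a (-1.88, adjusted p = 0.0144) fell, while Cav1 did not pass (adjusted p = 0.257). Osbpl3, Net1, Agpat4 and Vstm4 were higher by 0.63 to 0.83, and 1 of 2 other Net1 probes had the same sign. Of these Agpat4 passed by the trend (0.91, adjusted p = 0.00438). Lmcd1 and Itprip had changes of -1.37 and -0.93, and Egfr lay between these. The cell cycle (adjusted p = 0.000376), immediate early (adjusted p = 0.00637) and Atf4 (adjusted p = 0.0439) lists were lower in the mean, each with an adjusted p of 0.954 with an estimated correlation. The mean change of the cell cycle list was -0.05 in MEF, -1.79 in NSC and 0.18 in BMC. By the trend that list also passed as lower in MEF (adjusted p = 0.0411, adjusted p = 0.857 with an estimated correlation), with a median of -0.37 at 24 h and 21 of 24 lower. In MEF no member of it passed by the trend, on its own or adjusted over the list alone. The mean change was -0.57, -0.29 and -0.04 for immediate early genes and -0.65, 0.08 and -0.03 for Atf4 targets. By the trend 21, 3 and 10 of their members fell in the mean, 24, 4 and 11 when adjusted over the list alone and 6, 1 and 1 with the wild-type trend subtracted.

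Tests of the difference between cell types passed 2 probes for MEF against NSC, 0 for MEF against BMC (limma, with 711 at an unadjusted p under 0.05 and 535 called by the trend) and 5 for NSC against BMC. The 2 became 0 without the 12 h MEF array, with the authors' values, without background correction or with an offset of 50, and 243 without the 6 h NSC array. Cav1 rose more in NSC than in MEF or BMC, with differences of -4.40 ± 0.51 (MEF minus NSC, adjusted p = 0.0317) and 4.19 ± 0.51 (NSC minus BMC, adjusted p = 0.0325). The changes of Ltf, which was lower in BMC and below background in NSC, and of Kcnip3 (-2.63 in NSC, below background in BMC) differed between NSC and BMC (both adjusted p = 0.0343). By the trend MEF and NSC differed in 1708 probes and NSC and BMC in 1668. With the wild-type trend subtracted, which was possible for MEF and NSC only, these counts were 74 and 609. For MEF against BMC the count was then 63. Yet 213 probes rose in both MEF and NSC by the trend where 113 would by independence, and 182 fell in both against 86.4, while 45 and 46 went opposite ways against 108 and 90.5. MEF and BMC shared 13 rises against 1.53 and 3 falls against 4.65, and NSC and BMC shared 3 rises against 2.98 and 0 falls against 10.8. Opposite ways went 3 and 3 in MEF and BMC against 5.81 and 1.22, and 3 and 3 in NSC and BMC against 11.3 and 2.84. The cell types share the error of each probe and a gene can have several probes. Calls are therefore not independent, and these expected counts are only a rough yardstick. Across probes, which are not independent replicates, the mean changes of MEF and BMC correlated with r = 0.184 (Spearman 0.115). This r was above all 15 values obtained with another time as reference and larger than each in size. The induced Pou5f1 probes were included, which favours the 0 h references. The values for MEF and NSC (r = 0.0896) and for NSC and BMC (r = 0.0112) were reached in size, whatever the sign, by 10 and 13 of 15 such choices.

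Over 24 h of treatment fewer probes differed at least 2-fold in wild-type MEF (33) than in wild-type NSC (234), counts that moved with the processing. With 1 array per time, treatment is not separated from culture time or array noise. Among detected genes with a name, the largest differences in wild-type MEF were those of Dhdds (at least 1.97-fold), Dctn1, Olfr318 (at least 1.24-fold), Col5a2 (1.15) and Psmc6 (at least 1.63-fold) upward and of Ndrg2 (at least 1.62-fold), Erich5 (-1.23), Fam161a (at least 1.37-fold), the interferon-induced Bst2 (-1.18) and Rhbdl2 (-1.17) downward. In wild-type NSC the synaptic pentraxin gene Nptx2 (2.93), the VEGF receptor gene Flt1 (at least 4.01-fold), Gbx2 (2.57), the glucocorticoid-responsive Fkbp5 (2.14) and Serpina3n (2.13) were higher. Mfap4 (at least 4.12-fold), Rnd3 (-2.30), Actc1 (-2.27), Draxin (-2.25) and Cntnap4 (at least 3.33-fold) were lower. On the 0 h arrays the transgenic and wild-type lines already differed at least 2-fold in 1195 probes in MEF and 1399 in NSC, so the induced line was always set against its own 0 h array.

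ESC differed from the uninduced somatic cells in many transcripts and gave the levels a pluripotent cell reaches. Probes at least 2-fold apart numbered 5479 against MEF, 6095 against NSC and 7167 against BMC at 0 h. The pluripotency-associated genes Dppa5a (at least 562-fold), Esrrb (at least 199-fold), Dppa4 (at least 190-fold), Fbxo15 (at least 140-fold) and Tex19.1 (at least 119-fold) led the genes higher in ESC than in MEF. Chchd10 (at least 391-fold) and Dnmt3l (at least 246-fold) joined them against NSC. MEF led in the matrix genes Lox (at least 317-fold), Col1a1 (at least 298-fold), Col6a1 (at least 268-fold) and Mgp (at least 239-fold). Ptn was also higher in MEF (at least 230-fold). NSC led in Ptn (at least 466-fold), Ednrb (at least 293-fold), Mt3 (at least 266-fold), Kcnc1 (at least 126-fold) and Tmem176b (at least 121-fold). BMC led in the lysozyme genes Lyz1 (at least 728-fold) and Lyz2 (at least 633-fold), S100a8 (at least 555-fold), Lgals3bp (at least 498-fold) and C1qb (at least 382-fold). Against BMC, ESC were higher in Dppa5a (at least 629-fold), Esrrb (at least 225-fold), Dppa4 (at least 215-fold) and Fbxo15 (at least 158-fold).

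Within 24 h of induction no pluripotency gene other than Pou5f1 passed as higher. Pou5f1 is the induced gene, so its own rise was set by the design. Whether its probes tell the transgene from the endogenous gene was not tested. Of the 26 measured members of the pluripotency list, Pou5f1 alone rose in each cell type in the step test, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.788 in MEF, 0.869 in NSC and 0.83 in BMC). The list's medians were -0.01, -0.04 and -0.05 at 24 h in MEF, NSC and BMC. These mostly reflect background, since 20, 19 and 20 of the 26 members lay below it at both 0 and 24 h. Besides Pou5f1, the members detected after induction but not at 0 h were Lin28a on 1 MEF array and Klf4 on 2 BMC arrays. By the trend Dnmt3l fell in MEF (at least 1.38-fold, adjusted p = 0.032), and Esrrb (-1.16), Zfp42 (at least 1.24-fold) and Klf5 (at least 1.32-fold) fell in NSC, close to background, but none of these 4 passed when adjusted over the list alone. When adjusted over the list alone the step test also passed 1 lower member in BMC, Ooep, which was below background on all 4 arrays. Of 727 probes detected in ESC but on no somatic array at 0 h, 44, 60 and 52 were detected in MEF, 34, 21 and 48 in NSC and 20, 32 and 34 in BMC at 6, 12 and 24 h. In wild-type MEF and NSC 38 and 33 were at 24 h. Across genes, the change at 24 h correlated with the difference between ESC and the somatic cells by r = 0.0366 in MEF, -0.207 in NSC and -0.0211 in BMC, after 0.23 at 6 h in NSC. The somatic level came from the wild-type 0 h array in MEF and NSC and from the 0 h arrays of the other 2 cell types in BMC, so no array entered both sides. For the 24 h change of wild-type cells r was -0.0273 in MEF and -0.0135 in NSC.

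The lists not described above stayed short of the threshold in the step test of the 3 cell types and of their mean. The lowest adjusted p over the 3 cell types and their mean was 0.788 for epithelial markers, of which Krt7 (at least 1.78-fold) and Krt18 (below background at 0 and 24 h) fell in MEF by the trend. It was 0.788 for trophectoderm markers, 0.521 for primitive endoderm and mesendoderm markers, 0.201 for p53 targets and senescence genes, 0.0806 for glycolysis and hypoxia genes, 0.459 for histone and DNA methylation regulators and 0.805 for ribosomal proteins. By the trend the glycolysis and hypoxia list passed as lower in the mean (adjusted p = 0.044, adjusted p = 0.747 with an estimated correlation). By the trend with fry the histone and DNA methylation and the ribosomal lists passed as lower in NSC (both adjusted p = 0.0415). The p53 list differed between MEF and NSC (adjusted p = 0.0456, adjusted p = 0.71 with an estimated correlation). Within them, the p53 target Sesn1 rose (2.68 over 24 h, adjusted p = 5.16e-05) and Plk2 fell (-1.60, adjusted p = 0.000707) in NSC, and the demethylase gene Kdm6b rose (1.75, adjusted p = 0.00523). The fibroblast markers Thy1 (at least 4.1-fold at 24 h) and Vim (1.17, adjusted p = 0.0134) rose in NSC by the trend, 2 of 27 members, also 2 when adjusted over the list alone.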

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

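The tests of differences between lists, and the comparisons with wild-type arrays, with marker genes of other cells and with granulocyte genes, were chosen after the results were seen, while the tests of single probes, of other normalizations and of other reference times or time orders were set before.

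In 7 tests of single probes the change differed between cell types. The values below are fitted, and where a probe lay below background they are no measured folds. Cav1, detected on all 16 somatic arrays, changed by -0.26 in MEF and 4.14 in NSC (MEF minus NSC -4.40 ± 0.51, limma adjusted p = 0.0317), and NSC minus BMC was 4.19 ± 0.51 (adjusted p = 0.0325). Slc25a45, not detected in MEF after induction, had -0.91 in MEF and 1.70 in NSC (difference -2.61 ± 0.34, adjusted p = 0.0472). Igsf3 had 1.63 in NSC and -0.85 in BMC (2.49 ± 0.32, adjusted p = 0.0325), and a probe without a gene name, not detected in NSC after induction, had -3.17 and 0.13 (-3.30 ± 0.42, adjusted p = 0.0325). Ltf lay below background in NSC throughout and in BMC after induction, where it was at least 2.11-fold lower (fitted difference 1.80 ± 0.24, adjusted p = 0.0343). Kcnip3, not detected in BMC at any time, had -2.63 in NSC and 0.21 in BMC (-2.84 ± 0.39, adjusted p = 0.0343).

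The mean change of 16 pairs of list and cell types differed by camera at the preset correlation. For MEF minus NSC these were neuronal markers (1.11, adjusted p = 0.0281), cell cycle (1.74, 4.18e-06), p53 targets (-0.39, 0.0456), interferon response (0.81, 0.0272), NF-kB (-0.70, 0.0104), TGF-beta and serum targets (-0.95, 0.00792), Atf4 targets (-0.74, 0.00123) and oxidative phosphorylation (0.27, 0.0105). For MEF minus BMC they were interferon response (1.05, adjusted p = 5.63e-06), TGF-beta and serum targets (-0.71, 0.00792), immediate early genes (-0.52, 0.0086) and Atf4 targets (-0.62, 0.000232). For NSC minus BMC they were lymphoid, erythroid and progenitor blood markers (0.68, adjusted p = 0.026), cell cycle (-1.96, 1.65e-10), oxidative phosphorylation (-0.23, 0.0155) and cholesterol synthesis (-0.79, 0.0158). None of the 16 stayed past the threshold with an estimated correlation (adjusted p 0.710 to 0.832). By the trend the interferon difference between MEF and BMC did (adjusted p = 0.0409).

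The fall of cell cycle genes in NSC (median -3.51 at 24 h) was set against 3 technical explanations, and the values argue against each as far as the arrays reach. In wild-type NSC the median was 0.12 at 24 h, so treatment and culture time did not give it in that line. That reading rests on 1 array per time, and the 2 lines already differed at least 2-fold in 1399 probes at 0 h. Over 5 other ways to make the values, the median nearest 0 was -2.48. Neural stem and progenitor markers detected at 0 h had a median of 0.38, where a replacement of the neural cells by others needs a fall. The marker list also holds glial genes such as Gfap and S100b. It therefore cannot tell a shift from dividing to other neural cells apart from lower expression within the cells. A candidate explanation is that Oct4 lowers the expression of division genes in NSC, a hypothesis found and tested on the same data, while a difference in handling between these single cultures was not tested.

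The rise of interferon genes in MEF (median 1.68 at 24 h) did not appear in wild-type MEF (median -0.0901). Yet the median level was already 6.85 in wild-type MEF at 0 h, against 5.36 in the induced line at 0 h and 7.41 at 24 h, so an effect of treatment or culture time cannot be told apart. Neither can immune cells in the culture or a larger share of them. Of 19 myeloid and macrophage markers 12 lay below background on both arrays (median of all -0.23, or 0 with members at their bound). The 11 detected in wild-type MEF at 0 h went both ways in the induced line, 7 of them lower (median -0.34). Lyz2 (8.45 at 0 h, 7.94 at 24 h) and Laptm5 (8.02 and 7.13), the most abundant of them there, were lower. Its size stays open, since without background correction the median was 0.82, under the bound of 50 percent of the reported value that was set in advance, although its sign was kept under each of 5 other ways to make the values. Whether Oct4, or a response of the culture to the expression of the transgene, could drive it was not tested.

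The fall of granulocyte and progenitor genes in BMC cannot be told apart from an effect of culture time or treatment, because 0 wild-type BMC arrays were at hand. Other normalizations left a median of -0.46 or further from 0 for the progenitor list, just past 50 percent of the reported -0.90, while members below background set to their bound, or to 0 where both sides were below it, gave -0.31. A set of 20 granulocyte genes, written after the other BMC results were seen, had a median of -1.72 at 24 h over 17 measured members, all 17 lower and 16 of them at least 2-fold lower. The abundant S100a8 (14.53 at 0 h) changed by -2.11, S100a9 by -2.68 and Retnlg by -4.88. These values do not separate a loss of granulocytes from the culture, a candidate explanation, from lower expression within the cells, and no gate or sort is named in the labels that would remove them.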

How the results depend on the processing

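The trend counts as results of their own, their alternatives, the list tests by the trend, the list tests without the 24 h arrays and the list medians with members at their bound were chosen after seeing the data. All other alternatives were set before the data were examined. No paired analysis was possible because the labels do not pair any samples.

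The count of changed probes moved with the processing. For MEF (30) it was 16 with the authors' values, 14 with median scaling, 64 with no filter on detection, 533 with no cell line term, 2 with a treatment term shared with wild type, 1710 by the linear trend, 4 with wild-type arrays left out and 2 in a separate fit. For NSC (32) it was 19 with the authors' values, 96 with no cell line term, 3 with the shared treatment term, 3617 by the trend, 8 without wild type and 0 in a separate fit. For BMC (5) it was 3 with detection on at least 3 arrays, 2 with the shared treatment term, 120 by the trend, 3 without wild type and 2 in a separate fit. The mean over cell types (10) gave 6 with the authors' values, 6 without background correction, 4 with median scaling, 18 with no cell line term, 2 with the shared treatment term, 2785 by the trend, 4 without wild type and 6 with an intensity trend and robust prior. MEF against NSC (2) gave 0 with the authors' values, 0 without background correction, 0 with an offset of 50, 148 with no cell line term, 1 with the shared treatment term, 1708 by the trend and 1 with the robust prior. A separate fit and a fit without wild type have fewer arrays to estimate the spread. The trend looks for another shape of change than the step test. With no cell line term the transgenic and wild-type lines of a cell type share an intercept, so differences between the lines enter the change. For the other settings the cause was not tested.

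The step test was repeated without each of 13 arrays. The 3 induced-line arrays at 0 h, each the only reference of its line, were not left out there. This gave 6 to 425 probes for MEF. The highest was without the 6 h MEF array, the lowest without the 12 h BMC array. The count was 8 without MEF at 12 h, 10 without MEF at 24 h, 10 without BMC at 6 h, 6 without BMC at 24 h, 47 without NSC at 6 h, 10 without NSC at 12 h and 10 without either wild-type MEF array. For NSC the range was 14 (without BMC at 6 or 12 h) to 986 (without NSC at 6 h), with 16 without MEF at 12 h, 17 without NSC at 12 h, 59 without NSC at 24 h and 15 without either wild-type MEF array. For BMC it was 5 to 27 (without BMC at 6 h). For the mean it was 4 (without MEF at 12 or 24 h, BMC at 12 h or either wild-type MEF array) to 63 (without MEF at 6 h), with 38 without NSC at 6 h and 5 without BMC at 24 h or NSC at 12 h. For MEF against NSC it was 0 (without MEF at 12 h, any BMC array at 6, 12 or 24 h, NSC at 12 h or either wild-type MEF array) to 243 (without NSC at 6 h), with 152 without MEF at 6 h and 31 without NSC at 24 h.

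The trend count in MEF (1710) was 1065 with the authors' values, 177 net of the wild-type trend and 396 (without MEF at 24 h) to 2069 (without NSC at 6 h), with 859 without MEF at 0 h. In NSC (3617) it was 1301 net of the wild-type trend and 555 (without NSC at 24 h) to 3740 (without NSC at 12 h), and median scaling gave 1483 higher and 2085 lower in place of 1851 and 1766. In BMC (120) it was 54 with the authors' values and 23 (without BMC at 24 h) to 130 (without NSC at 0 h), with 73 without BMC at 0 h. Net of the wild-type trend, the 1708 probes for MEF against NSC became 74 and the 2785 for the mean became 415.

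Of the 14 list calls, 0 passed with an estimated correlation and 0 with fry, both in the step fit. With fry by the trend, all of them passed but oxidative phosphorylation in NSC (adjusted p = 0.0699). Over all lists and contrasts camera by the trend passed 22, of which 13 were among the 14. With an estimated correlation it passed 1, also among them. Without the 24 h arrays 8 passed, 6 of them among the 14. The cholesterol list in NSC reversed without the 24 h arrays (adjusted p = 0.966, range over its alternatives 3.64e-10 to 0.966), and its median was 0.65, -0.84 and -2.09 at 6, 12 and 24 h. The cause was not tested. Cell cycle in NSC passed under 6 of 9 alternatives (8.18e-24 to 0.954), interferon in MEF under 5 (1.77e-10 to 0.954), progenitor blood markers in BMC under 6 (5.1e-10 to 0.954) and oxidative phosphorylation in NSC under 1 (0.0262 to 0.954).

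Counts of probes at least 2-fold from 0 h at 24 h were, with a limit of 1.5-fold, 3981 in MEF, 5125 in NSC, 1186 in BMC, 531 in wild-type MEF and 1300 in wild-type NSC. With an offset of 50 they were 1093 in MEF, 151 in BMC, 3 in wild-type MEF and 98 in wild-type NSC. With the authors' values they were 746 in BMC, 401 in wild-type MEF and 663 in wild-type NSC, and with median scaling 71 in wild-type MEF. The change of Pou5f1 by its 2 probes was 5.48 and 5.49 in MEF, 3.54 and 3.90 in NSC and 3.97 and 4.10 in BMC without background correction. It was 6.49 and 8.25 in NSC and 6.98 and 7.16 in BMC with the authors' values, because the level at 0 h is set by the background there. ESC counts against MEF, NSC and BMC stayed within 1.5 times, although median scaling split MEF into 3703 higher and 2062 lower in place of 2835 and 2644.

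None of the named changes that could be computed reversed under the 13 settings that changed the values, the filter or the model, or with an array left out. That was largely fixed in advance and is weak evidence of robustness. Genes were named only with the same sign at all later times, so leaving out a later array could not turn a line's change. The filter, the prior, wild-type arrays and arrays of other lines bear on the error or p of a line's change, not its sign. Other values, no cell line term, the shared treatment term and the trend could turn it. The named changes that could be computed were 80, but 71 with detection on at least 3 arrays. Of these 71, 69 kept their side of the threshold and 2 lost it. With the authors' values 52 kept their side of the threshold and 28 lost it, and by the trend 41 kept it, 24 lost it and 15 gained it. With the shared treatment term 39 kept and 41 lost it, and without wild type 45 kept and 35 lost it. A separate fit covered 60, of which 24 kept and 36 lost it. The background limits every fold of a probe below detection, which is why these are given as lower bounds.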

Other observations

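The tests of reference times and time orders below were set before the data were examined, and the comparison of ESC-restricted probes with wild-type arrays was chosen after the results were seen.

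Of the 727 probes detected in ESC and on no somatic array at 0 h, those that reached 2-fold over the lowest detected signal numbered 2, 2 and 5 in MEF, 2, 6 and 13 in NSC and 0, 0 and 0 in BMC at 6, 12 and 24 h, and 0 and 1 in wild-type MEF and NSC at 24 h.

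Taking another time as the reference of its line gave a yardstick for the counts of the step test. For MEF (30, highest other 218), NSC (32, highest other 1868) and BMC (5, highest other 39), 2 of 4 choices gave as many probes, and for MEF against NSC (2, highest other 584) 8 of 16. These choices are too few for a share under 0.05. For the mean over cell types 13 of 64 choices gave as many as the real 10 (highest other 752), so chance is not excluded. The choices with several times the real count took 24 h as the reference, which points to a structure of the samples in which the 24 h arrays stand apart.

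For the trend, 1 of 24 orders of the 4 times, the real one, gave as many probes in MEF (1710, highest other 1273). The same held in BMC (120, highest other 81). In NSC 2 of 24 orders gave as many (3617, highest other 4065, with 0 and 6 h exchanged). The count ignores direction, so an order and its reverse are close to duplicates. The reversed order called 1273 probes in MEF and 71 in BMC. With such duplicates the orders are too few for a share under 0.05. Drift of a single culture over time could also favour the real order. A chance order is therefore not excluded in any of the cell types.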
